A study of Drosophila melanogaster with 12 samples.

How the data were processed

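Gene expression was measured by RNA sequencing in whole third-instar larvae of Drosophila melanogaster. The wild-type control line and a line null for Mlx (mlx1) were each collected on a low sugar and a high sugar diet. Larvae raised on 10% yeast were moved either to fresh 10% yeast and collected 1.5 h later, or to 10% yeast with 20% sucrose and collected 8 h later. Each of the 4 groups has 3 libraries, lettered A, B and C. Diet therefore goes together with the hours after transfer, and each diet contrast holds both. The column names of the table also end in L2 for every low-sugar and L3 for every high-sugar library. The meaning of this tag is not given, and if it marks a lane or batch, that too goes together with diet. A time or batch effect that adds equally in both genotypes drops out of the genotype by diet interaction. There is 1 control and 1 mutant line, so genotype differences, those in the diet responses included, cannot be told apart from other differences between the lines.

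The authors deposited 1 table of raw read counts, whole numbers per exon of each gene for the 12 libraries, not normalized for depth or exon length. Per the labels, the tools were BWA 0.5.9, SAMtools and HTSeq 0.6.1. The genome build, the annotation release and the strand setting are not given in the sources used here. Libraries were made from polyadenylated RNA. The table holds 82046 exon entries under 16413 gene names. Of these names 11754 are current fly gene symbols, 4300 are older symbols matched to a current one and 359 matched none. The names of the table are used here, with the current symbol in parentheses where it differs. A further 42 entries without a gene name hold at most 0.0148% of a library's counts. Exon entries that overlap another entry make up 36.0% of the table. Of the overlapping entries 67.2% are 0 in every library, against 9.3% of the others, so reads were probably left uncounted in many overlapping exons. In 1810 genes every entry overlaps another, and their levels may be too low, which was not tested by gene. In 4 entries of 1 gene the label had been turned into a time of day, and the gene name was read from it. Pepck (Pepck1) was 0 in all 12 libraries and could not be tested.

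Counts were summed over the exon entries of each gene. Library totals ranged from 8924342 to 12507970 counts. Genes with low counts were removed by filterByExpr with the 4 groups, which left 10045 genes. A quasi-likelihood model of edgeR 4.0.16 (R 4.3.3, TMM normalization, robust estimation, 1 mean per group, 8 residual degrees of freedom) was fitted to all 12 libraries. Its common dispersion was 0.0619, and the normalization factors ranged from 0.961 to 1.048. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 fold changes are standard errors, the size of the fold change divided by the square root of the F statistic. Levels are TMM-normalized CPM with the SD of the 3 libraries. Positions are those of the table. The p-values measure the spread between these libraries, and the labels do not say whether the libraries of a group came from separate cultures.

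The contrasts were the diet response in wild type, the diet response in mutants, the genotype effect on low sugar, the genotype effect on high sugar, and the interaction, which is the mutant diet response minus that of wild type. The design, the alternatives, the 31 gene lists and the rule for naming genes were chosen before the data were examined. The rule names the genes with the largest changes among those called with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. It takes 8 in each direction for the wild-type diet response, the genotype effect on high sugar and the interaction, and 5 for the other contrasts. It adds up to 5 members of each described list by p, and 19 genes fixed by name. Most of these 19 also stand in the list of reported Mondo-Mlx targets, which the study partly chose on these samples. Such genes, sug, Zw and ATPCL among them, are therefore not independent evidence. For the interaction, the reading that the groups must not overlap in at least 1 genotype was settled after a first look at the data. Where many members were called, those named here were picked for keeping their call without any 1 library.

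The lists cover glycolysis, gluconeogenesis with trehalose and glycogen, the pentose phosphate pathway, fatty acid and triglyceride synthesis, lipolysis and beta-oxidation, mitochondrial respiration, the TCA cycle, and amylases with maltases. They also cover digestive serine proteases, polyol and aldehyde metabolism, serine, glycine and one-carbon metabolism, other amino acid metabolism, insulin signalling and growth, nutrient responsive transcription factors, and the circadian clock. Further lists are cytosolic ribosomal proteins, ribosome biogenesis, heat shock proteins, glutathione transferases with cytochromes P450, antimicrobial peptides, larval cuticle, ecdysone response, late larval secretions, and DNA replication. Markers of muscle, neurons, hemocytes, fat body, midgut and males, and genes reported as Mondo-Mlx targets complete them. They were written from general knowledge, some genes stand in more than 1 list, and the last was partly chosen by the study on these samples, so it is not independent evidence. A list was compared with all other genes by camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run as alternatives. Fry asks whether the genes of a list move, on balance, in 1 direction, without comparing them with other genes. For each list the members called are counted over all genes tested and adjusted over the list alone.

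Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, no filter and a stricter filter on low counts, the library letter as a block, a log2 fold change of at least 1, the exon with the highest mean in place of the sum, leaving out exons that overlap another gene, the 6 libraries of a contrast alone, and each library left out in turn. After the data were seen, the mean of the larval cuticle list as a covariate, a fit without 3 libraries that stood apart, and the block within the low-sugar libraries were added. The 3 libraries, A of both low-sugar groups and C of wild type on high sugar, were low in cuticle genes for their group. Mutant low-sugar library B, with a cuticle mean 1.16 above that of its group on the log2 scale, was kept in that fit. All contrasts were tested on simulated data with known changes in 200 genes. In these edgeR recovered 55% of 2-fold and 91% of 4-fold changes for the wild-type diet response, and 17.2% and 71.7% for the interaction. Between 1.1% and 5.8% of its calls were unchanged genes, against 7.8% to 14.3% for DESeq2. These data drew each gene by itself from the dispersions of edgeR, without spread shared between genes. The rates may therefore differ in the real libraries, and the setting may favour edgeR. GC content was not examined. The groups of 3 were not tested for outlying libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.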

Results

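RNA was sequenced from 12 libraries of whole larvae, 3 each of wild type on low sugar, mlx1 mutants on low sugar, wild type on high sugar and mlx1 mutants on high sugar. The total counts of libraries A, B and C were 10020927, 10488754 and 9922743 in wild type on low sugar. They were 12507970, 11297719 and 9657715 in mutants on low sugar, 8924342, 9863889 and 11032921 in wild type on high sugar and 9306899, 10816936 and 9053479 in mutants on high sugar. Pearson's r of log2 CPM between libraries, taken across genes, which are not independent replicates, was 0.932 to 0.988 within groups and 0.879 to 0.972 between groups. The comparisons below ask which genes differ between larvae on high and low sugar. They also ask which of these differences change in mutants lacking Mlx, the partner of the sugar-sensing transcription factor Mondo. High-sugar larvae were collected 8 h and low-sugar larvae 1.5 h after transfer. A rise or fall on sugar below therefore names the diet contrast, which also holds the hours and the L2 and L3 tag.

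Mlx itself, listed as bigmax at 3R:23113088-23114248, was nearly absent from the mutants. It stood at 27.0 ± 0.73 CPM in wild type and 0.694 ± 0.201 CPM in mutants on low sugar, and at 32.6 ± 1.92 and 0.893 ± 0.168 CPM on high sugar (SD, n = 3). Its log2 fold change was -5.24 ± 0.19 on low sugar (adjusted p = 2.95e-08) and -5.18 ± 0.18 on high sugar (adjusted p = 3.08e-08). Exon 1 (23113088-23113441) had 454 reads in the 6 wild-type libraries and 0 in the 6 mutant ones, which is at least 160-fold lower over the group by the limit of 3 counts that a count of 0 allows. Exon 2 (23113507-23113907) had 925 and 1, a ratio of 981 (95% interval 176 to 38800), and exon 3 (23114050-23114248) had 400 and 49, a ratio of 8.66 (6.42 to 11.9). These intervals cover counting error only. The gene did not change with diet in either genotype by the call threshold.

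Libraries of the same group differed in the expression of larval cuticle genes, which are made around the moult. The list's mean was lowest in library A of both low-sugar groups, at 4.56 and 3.87 on the log2 CPM scale, and in library C of wild type on high sugar, at 3.56. The first component of the deviations from the group means, computed on the other genes, carried 51% of their spread. The cuticle list followed it (Pearson's r = -0.99, Spearman's rho = -0.97, 12 libraries, permutation within groups p = 0.0015 and 0.0039, adjusted over 30 lists 0.022 and 0.029). Without wild-type and mutant low-sugar library A, r was -0.98. Gluconeogenesis genes were higher where cuticle genes were lower (r with the component 0.9, rho 0.88, permutation p = 0.0039 and 0.0015, adjusted 0.023 for both, r = 0.83 without the same 2 libraries). Nutrient responsive transcription factors (r = -0.91, rho = -0.89, adjusted p = 0.022 and 0.023, r = -0.87 without mutant low-sugar libraries A and B) and ecdysone response genes (-0.85, -0.86, 0.033 and 0.023, -0.83 without mutant libraries B on low and A on high sugar) went with the cuticle list. By r but not after adjustment by rho, 7 more of the 30 lists followed the component. These were the TCA cycle (r = 0.87, adjusted p = 0.031), lipolysis (0.85, 0.023), pentose phosphate (0.84, 0.041), digestive proteases (0.84, 0.041), polyol metabolism (0.84, 0.041), neurons (-0.84, 0.023) and antimicrobial genes (0.61, 0.041). Several lists called below thus also vary between libraries of 1 group.

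**Figure D1:**
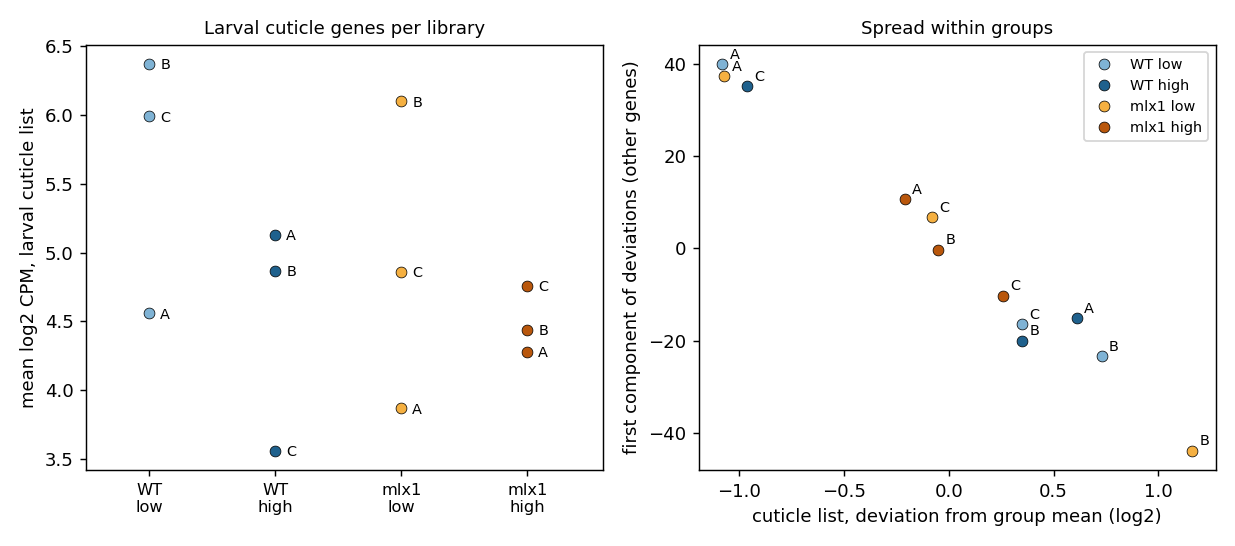
Left, the mean log2 CPM of the larval cuticle list in each library by genotype and diet, each point 1 library with its letter. Right, the first component of the within-group deviations of the other genes (vertical axis) against the deviation of the cuticle list from its group mean on the log2 scale (horizontal axis), with r = -0.99 over 12 libraries.

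In wild-type larvae most measured fatty acid and triglyceride synthesis genes were higher on high sugar at 8 h than on low sugar at 1.5 h. Fatty acid synthase (CG3523, FASN1, 2L:3056598-3068177) rose from 1510 ± 220 to 9700 ± 1850 CPM (SD, n = 3), a log2 fold change of 2.68 ± 0.19 (adjusted p = 4.12e-06). Acetyl-CoA synthase (AcCoAS, 3L:21263822-21273343) rose 9.13-fold, the NADPH-making dehydrogenase Zw (X:19561333-19566386) 6.74-fold from 44.1 ± 9.74 to 297 ± 26.0 CPM, and the sugar-responsive transcription factor sug (2R:8812072-8818149) 7.81-fold. The lipase brummer (bmm, 3L:14769596-14779512) fell by 1.02 ± 0.15 on the log2 scale (adjusted p = 0.000748). In all, 2318 of 10045 genes changed, 1154 higher and 1164 lower, of which 594 changed by at least 1 on the log2 scale. The count was 1423 without low-sugar library B (681 higher and 742 lower) and 1437 without high-sugar library B (747 higher and 690 lower). The balance of directions moved with the processing. RLE factors gave 1345 higher and 1050 lower, upper-quartile factors 1135 and 1161, DESeq2 1473 and 1155, and the cuticle covariate 1225 and 1696.

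The largest rise by the naming rule was that of the UDP-glycosyltransferase CG5724 (Ugt37A2, 3R:8565364-8567139), from 2.0 ± 0.726 to 94.6 ± 44.8 CPM, a log2 fold change of 5.56 ± 0.65. The neighbouring genes CG1638 and CG1774 (3R:27418525-27420441, an acyl-CoA thioesterase family member) rose by 4.59 ± 0.36 and 4.36 ± 0.18, CG14205 (an acyltransferase family member) by 4.66 ± 0.7, and the glycogen-binding phosphatase subunit CG9238 (Gbs-70E, 3L:14534037-14544075) by 3.59 ± 0.19. CG15369, a cystatin-like gene, fell by 4.47 ± 0.49 on the log2 scale, and CG14852 fell by 3.15 ± 0.15. The amylase Amy-p (2R:13006214-13007808) fell by 3.28 ± 0.73 (adjusted p = 0.0125, but 0.0961 in a fit of the 6 wild-type libraries alone), and its reads cannot be fully told from those of its paralog Amy-d.

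Of the 16 fatty acid and triglyceride synthesis genes 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 fold change of 1.02. Among them were ACC (2R:3861620-3879367), which makes malonyl-CoA, by 2.54 ± 0.17, ATPCL (2R:11881036-11888795), which makes cytosolic acetyl-CoA, by 2.64 ± 0.26, desat1 (3R:8265322-8273338) by 2.55 ± 0.15 and Gpdh (Gpdh1, 2L:5943643-5948843) by 1.95 ± 0.12. This list also passed with an estimated correlation (adjusted p = 3.1e-21, and 0.01 with an estimated correlation). Of 7 pentose phosphate genes 6 rose (6 adjusted over the list alone; adjusted p = 8.7e-11, and 0.1 with an estimated correlation), among them Pgd (X:2039169-2042599) by 1.98 ± 0.13, the transaldolase Tal by 1.61 ± 0.15 and the transketolase CG8036 by 1.65 ± 0.17. In glycolysis 7 of 12 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 9.6e-05, and 0.22 with an estimated correlation). Pgi was higher by 1.47 ± 0.14 and pyruvate kinase (PyK) by 1.35 ± 0.16. In gluconeogenesis, trehalose and glycogen metabolism 10 of 13 rose and 0 fell (11 and 1 adjusted over the list alone; adjusted p = 4.7e-10, and 0.13 with an estimated correlation). They included the trehalose transporter Tret1-1 by 1.01 ± 0.09, UGP by 1.68 ± 0.19 and the trehalose phosphatase CG5171 by 2.12 ± 0.13. Of the 15 genes reported as Mondo-Mlx targets 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 1.95 (adjusted p = 4e-24, and 0.0044 with an estimated correlation), a list partly chosen on these samples.

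Part of the lipolysis genes fell, and genes of amino acid metabolism went both ways. In lipolysis and beta-oxidation 0 of 19 rose and 5 fell (0 and 5 adjusted over the list alone; adjusted p = 0.029, and 0.47 with an estimated correlation), with the acyl-CoA dehydrogenase CG12262 (Mcad) lower by 1.43 ± 0.17 and the thiolase yip2 by 0.87 ± 0.1. That list was not called without low-sugar library A (adjusted p = 0.082), high-sugar library A (0.1) or high-sugar library B (0.053). In serine, glycine and one-carbon metabolism 3 of 14 rose and 7 fell (3 and 8 adjusted over the list alone; adjusted p = 0.0088, and 0.32 with an estimated correlation). The sarcosine dehydrogenase CG6385 (Sardh, 2R:13641060-13643927) fell by 2.53 ± 0.11, from 130 ± 6.94 to 22.5 ± 0.856 CPM, the glycine methyltransferase CG6188 (Gnmt) fell by 2.29 ± 0.2, and the phosphoserine phosphatase aay rose by 2.25 ± 0.18. Of 21 other amino acid genes 4 rose and 7 fell (4 and 8 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.16). Within it the proline-making enzyme CG7470 (P5CS) rose by 2.33 ± 0.18, while the tryptophan and tyrosine degrading enzymes v and hgo fell by 1.42 ± 0.12 and 1.19 ± 0.17.

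Most ribosome biogenesis genes fell, while part of the insulin and growth genes rose. In ribosome biogenesis 17 of 20 fell and 1 rose (18 and 1 adjusted over the list alone; adjusted p = 4.7e-10, and 0.22 with an estimated correlation), with the nucleolar proteins fibrillarin (Fib) lower by 1.06 ± 0.13 and Surf6 by 1.04 ± 0.14. In DNA replication 10 of 18 fell and 0 rose (13 and 0 adjusted over the list alone; adjusted p = 1.7e-05, and 0.22 with an estimated correlation). PCNA (mus209) was lower by 1.09 ± 0.14 and Mcm6 by 0.58 ± 0.1. Of 86 ribosomal protein genes 14 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.19 (adjusted p = 0.0039, 0.57 with an estimated correlation, and 0.053 without high-sugar library B). Among insulin and growth genes 8 of 19 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.00011, and 0.18 with an estimated correlation), with the activin-like ligand daw (2L:2805261-2812376) higher by 1.34 ± 0.13, the adipokinetic hormone receptor GRHR (AkhR) by 1.87 ± 0.18 and the translation inhibitor Thor (2L:3478434-3479612) by 1.16 ± 0.2. Of 12 nutrient responsive transcription factors 6 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 8.9e-05, and 0.024 with an estimated correlation), among them sug, cbt (2L:476446-479688) by 1.22 ± 0.25 and Mondo (Mio, 2L:21286078-21310050) by 0.72 ± 0.12.

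Part of the gut and detoxification genes rose, and part of the cuticle genes fell. Of 25 digestive proteases 9 rose and 0 fell (14 and 0 adjusted over the list alone; adjusted p = 4.8e-08, and 0.32 with an estimated correlation). The gene thetaTry was higher by 2.05 ± 0.25 and alphaTry by 1.25 ± 0.17. Of 14 midgut markers 10 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 4.3e-07, and 0.19 with an estimated correlation). Of 76 cuticle genes 18 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -1.34 (adjusted p = 6e-07, 0.46 with an estimated correlation, 0.072 by fry, and 0.075 with the cuticle covariate), for example Cpr11B by -0.72 ± 0.16 and obst-E by -1.11 ± 0.24. The covariate is the mean of the cuticle list itself, so the loss of that list's call with it is largely built in. With the cuticle mean as a covariate, the medians of the protease and midgut lists moved from 0.74 to 0.37 and from 1.03 to 0.72. Of 40 glutathione transferases and cytochromes P450 21 rose and 3 fell (23 and 3 adjusted over the list alone; adjusted p = 2e-09, and 0.19 with an estimated correlation). GstE7 was higher by 2.5 ± 0.23 and Cyp28d1 lower, at -1.67 ± 0.14. In amylases and maltases 5 of 14 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.022, 0.46 with an estimated correlation, 0.22 with the cuticle covariate and 0.15 without 3 libraries apart). Mal-A8 was higher by 2.81 ± 0.23 and Mal-A1 by 2.42 ± 0.27. That list was not called without low-sugar library C (0.11) or high-sugar library C (0.072). In polyol and aldehyde metabolism 4 of 11 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.048, 0.41 with an estimated correlation, and 0.17 with the cuticle covariate). It was also lost with at least 5 CPM in 3 libraries (0.053), with the letter as a block (0.064), by the exon with the highest mean (0.071) and without exons overlapping another gene (0.07). It was lost without low-sugar library B (0.07) or C (0.083) or high-sugar library C (0.086), and Aldh rose by 1.39 ± 0.17 within it.

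Of 5 late larval secretion genes 3 rose and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.0088, 0.17 with an estimated correlation, and 0.2 without a filter on low counts), among them the paralogs ng1 by 2.44 ± 0.41 and ng2 by 2.43 ± 0.39. Of 4 fat body markers 1 rose, the adipokinetic hormone receptor GRHR (1 adjusted over the list alone; adjusted p = 0.048, and 0.38 with an estimated correlation). That list was not called without low-sugar library B (0.07) or C (0.099), or high-sugar library A (0.067) or B (0.07). Nor was it called with RLE factors (0.053), without a filter on low counts (0.35), with at least 5 CPM in 3 libraries (0.051), with the letter as a block (0.072), without exons overlapping another gene (0.054) or with the cuticle covariate (0.14), so it lost the call in 11 of 17 settings. The other lists were not called. The median was -0.07 for 57 mitochondrial respiration genes (0 higher, 1 lower, adjusted p = 0.66), 0.15 for 13 TCA cycle genes (adjusted p = 0.15), 0.32 for 6 clock genes (2 higher and 1 lower, adjusted p = 0.15) and -0.23 for 9 heat shock genes (0 higher, 2 lower, adjusted p = 0.35). It was 1.36 for 20 antimicrobial genes (0 higher, 1 lower, adjusted p = 0.5) and 0.03 for 18 ecdysone response genes (adjusted p = 0.6). Markers of muscle (2 of 14 higher, 1 lower, adjusted p = 0.083), neurons (0 of 13 higher, 1 lower, 0.56), hemocytes (1 of 11 higher, 0.11) and males (none of 2 called, 0.66) were not called either. Of the 31 lists 20 were called by camera, 3 of them with an estimated correlation, and 22 by fry. In none of the 76 list calls over the 5 contrasts did the median or the mean differ in sign from the test.

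Part of the same genes were also higher on high than on low sugar in mutants. In mutants sug rose 8.32-fold from 4.32 ± 0.289 to 35.9 ± 1.48 CPM (SD, n = 3, log2 fold change 3.06 ± 0.12, adjusted p = 6.11e-08), FASN1 (CG3523) 5.39-fold from 465 ± 92.1 to 2510 ± 248 CPM and the translation inhibitor Thor 6.2-fold from 190 ± 61.5 to 1180 ± 132 CPM. The growth regulators InR (3R:17395970-17445043), Sesn and Ilp6 rose by 1.38 ± 0.14, 1.45 ± 0.14 and 1.13 ± 0.2 on the log2 scale. No change was called for Zw (0.3 ± 0.15, adjusted p = 0.15), Pgd (-0.01 ± 0.13, 0.977), ATPCL (0.45 ± 0.25, 0.203) or cbt (-0.35 ± 0.43, 0.675). In all, 2941 genes changed, 1361 higher and 1580 lower, and 872 by at least 1 on the log2 scale. Among the largest rises were those of the immune-induced peptide genes IM4 (Dso1) by 5.5 ± 0.97 and Mtk (2R:11296351-11296618) by 5.14 ± 1.12. Mtk went from 1.0 ± 0.114 to 35.8 ± 26.8 CPM, a wide spread between libraries. CG10474 fell by 3.78 ± 0.34 and CG15369 by 3.48 ± 0.47 on the log2 scale.

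In ribosome biogenesis 19 of 20 genes fell in mutants and 1 rose (19 and 1 adjusted over the list alone; median -1.41, adjusted p = 2e-22, and 0.088 with an estimated correlation), with l(1)1Bi (Mybbp1A, X:523806-527666) lower by 1.88 ± 0.13 and the helicase pit by 1.68 ± 0.13. In DNA replication 13 of 18 fell (14 adjusted over the list alone; adjusted p = 1.8e-09, and 0.12 with an estimated correlation), for example PCNA (mus209) by 1.29 ± 0.14. In fatty acid synthesis 10 of 16 rose and 0 fell (11 and 1 adjusted over the list alone; adjusted p = 2.1e-09, and 0.077 with an estimated correlation). AcCoAS was higher by 2.29 ± 0.14 and the malic enzyme Men by 1.76 ± 0.14. Of 15 Mondo-Mlx targets 7 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 1.5e-08, and 0.077 with an estimated correlation). In gluconeogenesis, trehalose and glycogen 8 of 13 rose (9 adjusted over the list alone; adjusted p = 2.9e-05, and 0.33 with an estimated correlation), with the bisphosphatase fbp higher by 0.92 ± 0.12 and the second phosphoenolpyruvate carboxykinase gene CG10924 by 2.02 ± 0.26. In insulin and growth 12 of 19 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 2.5e-07, and 0.085 with an estimated correlation). Of 12 transcription factors 7 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.0011, and 0.077 with an estimated correlation), with CG18619 (REPTOR-BP), a growth-restraining factor, higher by 1.83 ± 0.19.

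Also in mutants, 17 of 40 glutathione transferases and cytochromes P450 rose and 2 fell (19 and 2 adjusted over the list alone; adjusted p = 6e-06, and 0.35 with an estimated correlation), with Cyp6w1 higher by 3.33 ± 0.33. Of 25 digestive proteases 9 rose (9 adjusted over the list alone; adjusted p = 0.00024, and 0.63 with an estimated correlation), with Jon65Aiii higher by 1.08 ± 0.11. Of 14 amylases and maltases 6 rose (6 adjusted over the list alone; adjusted p = 0.0011, and 0.41 with an estimated correlation), for example Mal-B2 by 1.72 ± 0.23. In polyol metabolism 4 of 11 rose (4 adjusted over the list alone; adjusted p = 0.013, and 0.41 with an estimated correlation). Late larval secretions rose in 3 of 5 genes and fell in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.0011, and 0.088 with an estimated correlation). Of 86 ribosomal protein genes 13 rose and 2 fell (1 and 1 adjusted over the list alone; adjusted p = 0.0011, and 0.72 with an estimated correlation). Of 20 antimicrobial genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0091, 0.72 with an estimated correlation, 0.15 by fry and 0.24 with the cuticle covariate), with Drs higher by 2.95 ± 0.58. The chaperones Hsp83 and Hsp68 fell by 2.17 ± 0.21 and 2.08 ± 0.38, while the heat shock list was not called (adjusted p = 0.099). The pentose phosphate list was not called (adjusted p = 0.76, median -0.07), nor were lipolysis (0.87) and the cuticle list (0.1, median -0.89). Of the 31 lists 14 were called by camera, 0 with an estimated correlation (7 at an unadjusted p under 0.05), and 16 by fry.

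The diet responses of both genotypes shared 540 genes higher in both, where independence would give 156.4, and 683 lower in both, where it would give 183.1. The second was 1142 with the cuticle covariate. Another 15 genes that rose in wild type fell in mutants, and 36 that fell in wild type rose in mutants. Pearson's r of the fold changes across genes, which are not independent replicates, was 0.54 and Spearman's rho 0.49.

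On low sugar, mutants already had less of several Mondo-Mlx targets. The transcription factor sug stood at 4.32 ± 0.289 CPM against 24.9 ± 3.04 in wild type (SD, n = 3), a log2 fold change of -2.53 ± 0.11 (adjusted p = 2.13e-07). The transcription factor cbt was lower by 3.47 ± 0.32 on the log2 scale, the ligand daw by 1.29 ± 0.13, FASN1 (CG3523) by 1.7 ± 0.18 and Gpdh by 0.91 ± 0.11. Genes higher in mutants included the serine protease family member CG1304 (X:20835554-20836446), at 49.8 ± 13.3 against 0.941 ± 0.696 CPM (log2 fold change 5.72 ± 0.46, adjusted p = 9.19e-05), and the lipase family members CG6271 (3R:22850690-22851831) by 4.52 ± 0.65 and Lip3 (3R:9195962-9197626) by 3.19 ± 0.46. Of these, CG6271 lies within 2 Mb of Mlx. CG3292 (2R:18091199-18093098) was higher by 3.67 ± 0.42. CG13560 (2R:19635096-19635741) was lower by 4.82 ± 0.58, and the cytochrome P450 gene Cyp6a2 (2R:2667254-2668996) fell from 102 ± 7.99 to 8.03 ± 3.16 CPM. In all, 361 genes differed, 183 higher and 178 lower in mutants, of which 157 by at least 1 on the log2 scale. Low-sugar libraries of the same letter had correlated deviations from their group means for A and B (0.74 and 0.69), and weakly for C (0.17). On high sugar these correlations were 0, 0.34 and -0.35 for A, B and C, and the labels do not say that the letters mark pairs. With the letter as a block within low sugar, chosen after the data were seen, 996 genes differed, 514 higher and 482 lower. With the letter as a block in all 12 libraries, as planned, 336 differed, 174 higher and 162 lower. The count was 180 without wild-type library B (77 higher and 103 lower), 201 without mutant library C (97 higher and 104 lower) and 122 (56 and 66) in a fit of the 6 libraries alone. DESeq2 gave 653, 337 higher and 316 lower, and with the cuticle covariate 296 were lower.

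Of 15 Mondo-Mlx targets 0 were higher and 8 lower (0 and 13 adjusted over the list alone; median -0.82, adjusted p = 1.7e-21, and 0.0069 with an estimated correlation), a list partly chosen on these samples. Of 12 transcription factors 3 were lower (3 adjusted over the list alone; adjusted p = 0.00017, and 0.035 with an estimated correlation). In fatty acid synthesis 7 of 16 were lower and 1 higher (9 and 1 adjusted over the list alone; adjusted p = 1e-05, and 0.16 with an estimated correlation), among them the lipid droplet protein Lsd-1 by -0.97 ± 0.14. ACC, at -0.89 ± 0.16, and Zw, at -0.82 ± 0.15, passed in all 12 libraries (adjusted p = 0.00855 and 0.00838) but not in a fit of the 6 libraries alone (0.0512 and 0.0879), nor did ACC by its exon with the highest mean (0.2). In lipolysis 4 of 19 were higher and 0 lower (9 and 0 adjusted over the list alone; adjusted p = 1.5e-06, and 0.28 with an estimated correlation), for example the lipase mag by 2.36 ± 0.33. Pentose phosphate genes were lower in 2 of 7 (2 adjusted over the list alone; adjusted p = 0.0033, 0.56 with an estimated correlation, 0.068 by fry, and 0.056 without mutant library B). Other amino acid metabolism had 5 of 21 higher and 1 lower (9 and 3 adjusted over the list alone; adjusted p = 0.028, 0.16 with an estimated correlation, 0.094 by the exon with the highest mean, and 0.059 without wild-type library B). Within it hgo was higher by 1.54 ± 0.17 and the glutamine synthetase Gs2 lower, at -1.0 ± 0.09.

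Further lists on low sugar were called with few of their genes called. Of 76 cuticle genes 1 was lower (1 adjusted over the list alone; median -0.68, adjusted p = 8.6e-07, 0.75 with an estimated correlation, and 0.31 by fry), and of 86 ribosomal protein genes 1 was lower (0 adjusted over the list alone; adjusted p = 0.0041, 0.79 with an estimated correlation, and 0.16 by fry). Of 5 late larval secretion genes 2 were lower (2 adjusted over the list alone; adjusted p = 0.0027, 0.16 with an estimated correlation, and 0.057 without a filter on low counts). The TCA cycle list had 1 of 13 genes higher (3 adjusted over the list alone; adjusted p = 0.0041, 0.76 with an estimated correlation, 0.17 by fry, and 0.094 without mutant library A). The heat shock list had 1 of 9 lower (2 adjusted over the list alone; adjusted p = 0.028, 0.65 with an estimated correlation, 0.1 without wild-type library C, 0.3 without mutant library A and 0.1 without mutant library B). It was also lost by fry (0.16), without a filter on low counts (0.062), with the cuticle covariate (0.16) and without 3 libraries apart (0.11). Muscle markers had 0 of 14 called by edgeR, 0 also adjusted over the list alone (adjusted p for the list = 0.047, 0.79 with an estimated correlation, 0.31 by fry, 0.056 with upper-quartile factors, 0.15 by the exon with the highest mean, 0.16 with the cuticle covariate, and up to 0.45 without wild-type library C). Outside the called lists, the trehalase gene Treh was higher by 1.26 ± 0.15, CG10924 by 2.37 ± 0.28 and Cyp6a8 by 2.82 ± 0.39. Of the 31 lists 12 were called by camera, 2 of them with an estimated correlation, and 7 by fry.

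On high sugar mutants had less of the pentose phosphate genes and of part of the fatty acid synthesis genes. Zw stood at 30.7 ± 2.02 CPM in mutants against 297 ± 26.0 in wild type (SD, n = 3), a log2 fold change of -3.28 ± 0.16 (adjusted p = 8.11e-08). Pgd was lower by 2.61 ± 0.13, ATPCL by 2.92 ± 0.27, desat1 by 2.0 ± 0.14 and ACC by 1.69 ± 0.16, and sug was lower by 2.44 ± 0.11. The lipase bmm went the other way, at 171 ± 23.0 against 34.2 ± 5.11 CPM, a log2 fold change of 2.32 ± 0.16 (adjusted p = 1.71e-06). In all, 1392 genes differed, 683 higher and 709 lower in mutants, of which 499 by at least 1 on the log2 scale. The count was 836 without wild-type library B (421 higher and 415 lower) and 825 without mutant library A (407 higher and 418 lower), and the number lower was 441 without mutant library C. With the cuticle covariate 2298 differed, 1097 higher and 1201 lower. Among the largest differences were those of Cyp4e3 (2L:9747839-9750071), higher by 7.67 ± 0.93 (344 ± 69.8 against 1.68 ± 0.272 CPM), CG17669 (Dnaaf3, a dynein assembly factor) by 7.03 ± 0.57 and CG3292 by 5.59 ± 0.47. Amy-p was higher by 5.05 ± 0.78 (428 ± 46.2 against 12.8 ± 12.9 CPM) and Cyp6a8 (2R:10774676-10776515) by 4.72 ± 0.41. The transcription factor cbt was lower by 5.05 ± 0.34, CG1774 by 4.3 ± 0.18, CG9238 (Gbs-70E) by 4.22 ± 0.2 and CG13560 by 4.0 ± 0.57.

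All 7 pentose phosphate genes measured were lower (7 adjusted over the list alone; median -1.9, adjusted p = 1.8e-19, and 0.04 with an estimated correlation). Of 15 Mondo-Mlx targets 11 were lower and 1 higher (12 and 1 adjusted over the list alone; adjusted p = 5.3e-26, and 0.0026 with an estimated correlation). In fatty acid synthesis 9 of 16 were lower and 1 higher (10 and 2 adjusted over the list alone; adjusted p = 4.1e-11, and 0.052 with an estimated correlation), with Lsd-1 at -1.8 ± 0.14 and AcCoAS at -1.54 ± 0.14. In lipolysis 9 of 19 were higher and 0 lower (11 and 0 adjusted over the list alone; adjusted p = 2.1e-09, and 0.13 with an estimated correlation). CG12262 (Mcad) was higher by 1.87 ± 0.17 and yip2 by 1.37 ± 0.1. In glycolysis 4 of 12 were lower and 1 higher (4 and 1 adjusted over the list alone; adjusted p = 0.032, and 0.55 with an estimated correlation), with Pgi at -1.24 ± 0.14 and PyK at -1.19 ± 0.16. That list was not called without wild-type library C (0.11), mutant library A (0.069), mutant library B (0.051) or the 3 libraries apart (0.05 after rounding). Of 12 transcription factors 4 were lower and 2 higher (5 and 2 adjusted over the list alone; adjusted p = 0.012, and 0.12 with an estimated correlation).

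Genes of amino acid metabolism differed in both directions on high sugar. Of 21 other amino acid genes 10 were higher and 5 lower (11 and 5 adjusted over the list alone; adjusted p = 0.0036, and 0.082 with an estimated correlation), with hgo (2L:11136393-11138565) higher by 3.29 ± 0.18 and Gs2 at -1.23 ± 0.09. In serine, glycine and one-carbon metabolism 5 of 14 were higher and 2 lower (7 and 3 adjusted over the list alone; adjusted p = 0.022, 0.51 with an estimated correlation, and 0.06 without wild-type library A), with Sardh (CG6385) higher by 2.51 ± 0.11. Of 20 ribosome biogenesis genes 12 were lower (18 adjusted over the list alone; adjusted p = 5.3e-08, and 0.47 with an estimated correlation), while of 86 ribosomal protein genes 9 were higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 6e-07, and 0.51 with an estimated correlation). Of 9 heat shock genes 3 were lower (3 adjusted over the list alone; adjusted p = 0.0031, 0.43 with an estimated correlation, and 0.25 without exons overlapping another gene), with Hsp83 at -1.58 ± 0.21. Among glutathione transferases and cytochromes P450 5 of 40 were higher and 15 lower (6 and 15 adjusted over the list alone; adjusted p = 0.0099, 0.55 with an estimated correlation, 0.086 by fry, 0.082 with at least 5 CPM in 3 libraries, 0.13 without 3 libraries apart, and 0.11 without wild-type library C). Cyp6a2 stood at -3.75 ± 0.27 and Cyp6w1 was higher by 2.39 ± 0.32. Midgut markers were lower in 5 of 14 (6 adjusted over the list alone; adjusted p = 0.0044, 0.51 with an estimated correlation, and 0.067 by fry), with thetaTry at -1.3 ± 0.24. Of 18 DNA replication genes 2 were lower (2 adjusted over the list alone; adjusted p = 0.0099, and 0.55 with an estimated correlation).

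Of 20 antimicrobial genes 3 were higher on high sugar in mutants (3 adjusted over the list alone; adjusted p = 0.0036, 0.55 with an estimated correlation, 0.13 by fry, and 0.084 without mutant library A). Of 4 fat body markers the lipophorin gene Rfabg was lower, at -1.35 ± 0.26 (1 adjusted over the list alone; list adjusted p = 0.032, 0.51 with an estimated correlation, 0.15 without a filter on low counts, 0.065 without mutant library A and 0.055 without mutant library C). Gluconeogenesis genes went both ways and the list was not called (3 of 13 higher, 5 lower, adjusted p = 0.45). CG10924 (Pepck2) was higher by 3.29 ± 0.28, and CG5171 was lower, at -1.93 ± 0.13. Of the 31 lists 16 were called by camera, 2 of them with an estimated correlation, and 15 by fry. The genotype effects of both diets shared 108 genes higher in mutants, where independence would give 12.4, and 93 lower, where it would give 12.6. The first was 68 without wild-type low-sugar library B, and the second was 60 without mutant low-sugar library C, 140 with DESeq2 and 149 with the cuticle covariate. The main counts rest on the fit without a block, and the overlap was not computed with the block within low sugar. Opposite calls were made for 10 genes higher on low sugar and 11 lower there. Over all 10045 genes, which are not independent replicates, Pearson's r of the genotype effects was 0.41 but Spearman's rho 0.04.

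**Figure D2:**
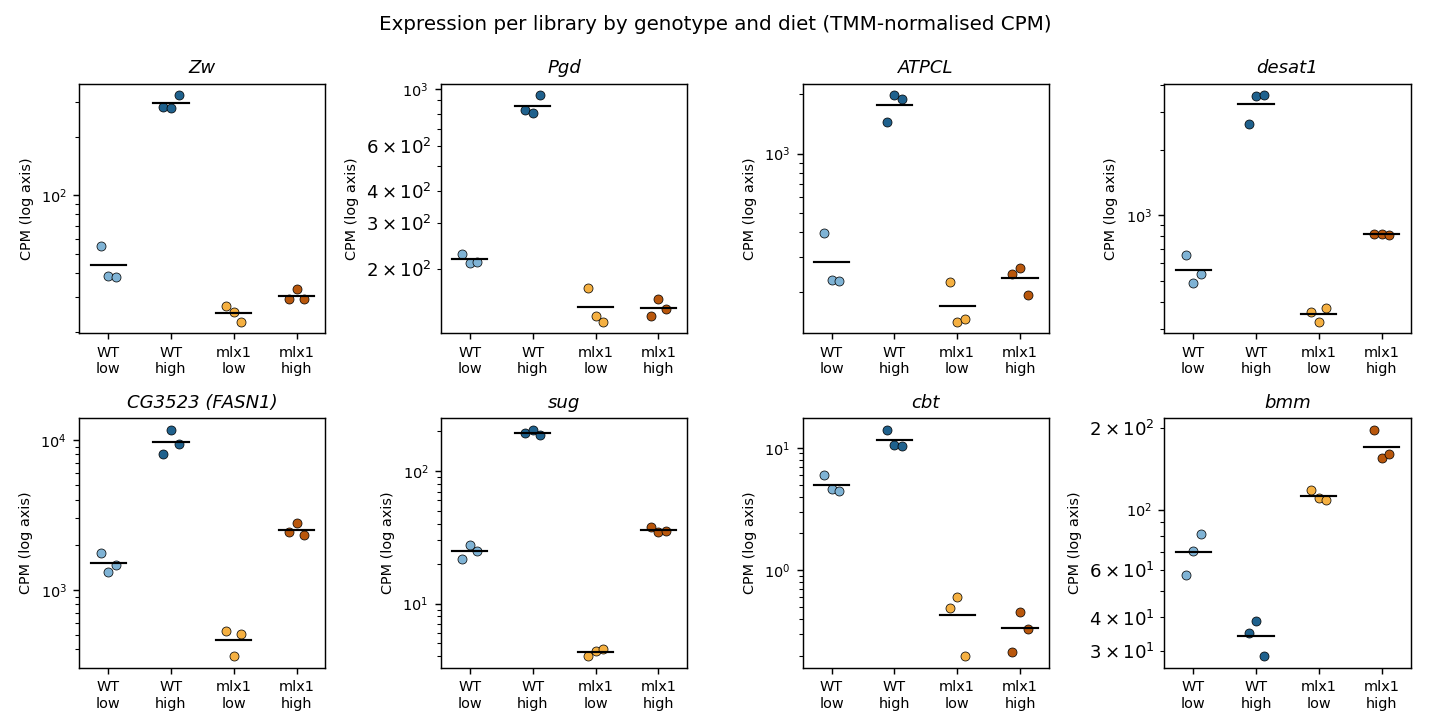
CPM per library on a log axis for 8 genes in the 4 groups of genotype and diet, points for libraries and lines for the group means. Zw rises from 44.1 to 297 CPM in wild type and is at 30.7 CPM in mutants on high sugar, while sug rises in both genotypes and bmm moves in opposite directions.

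The interaction tests the difference between the diet responses directly, between 1 control and 1 mutant line, so that other differences between the lines are not separated from the loss of Mlx. The pentose phosphate genes Zw and Pgd answered sugar less in mutants, by -2.46 ± 0.21 (adjusted p = 0.000117, n = 3 per group) and -1.99 ± 0.18 (adjusted p = 0.000169) on the log2 scale. So did the acetyl-CoA source ATPCL by -2.18 ± 0.36 and desat1 by -1.33 ± 0.2. The lipase bmm fell on sugar in wild type and rose in mutants, a difference of 1.63 ± 0.21 (adjusted p = 0.00166). Sardh (CG6385) fell less in mutants, with a difference of 1.91 ± 0.15 (adjusted p = 7.29e-05). For sug (0.09 ± 0.15, adjusted p = 0.752), daw (-0.15 ± 0.18, 0.66), FASN1 (CG3523, -0.26 ± 0.25, 0.566), ACC (-0.79 ± 0.22, 0.0545) and cbt (-1.57 ± 0.5, 0.0816) no difference between the responses was called.

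**Figure D3:**
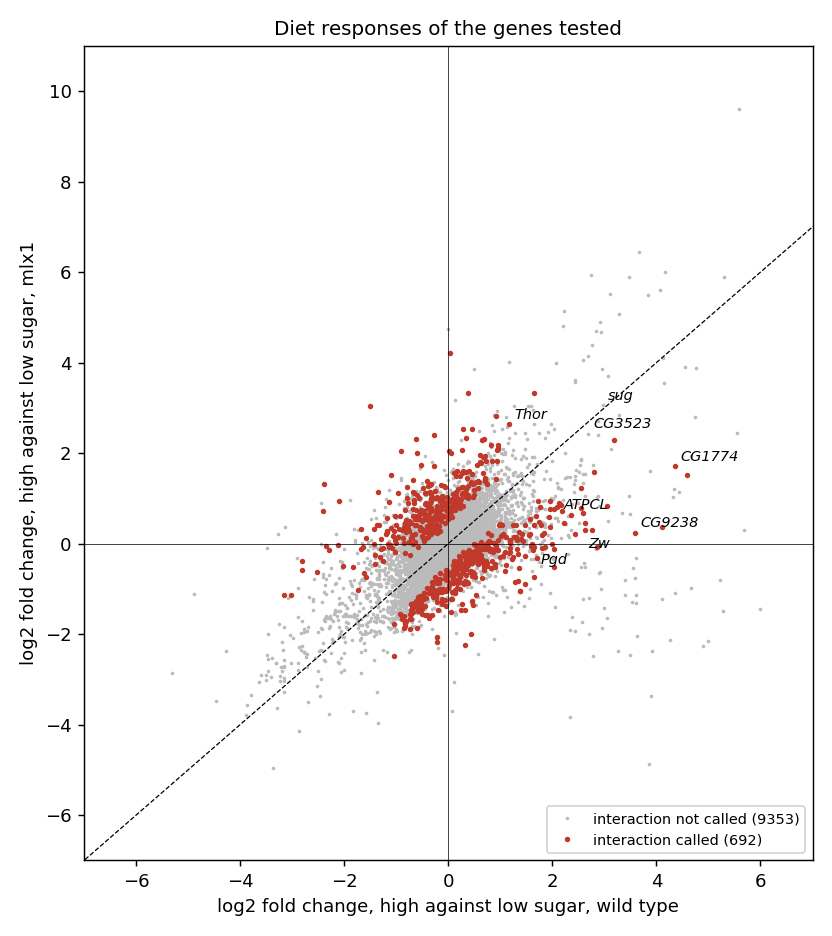
The diet response of each of 10045 genes as log2 fold change on high against low sugar, wild type on the horizontal and mlx1 mutants on the vertical axis, with the 692 genes with a called interaction in red and equal responses on the dashed line. Zw, Pgd, ATPCL and CG9238 lie near 0 for mutants, and sug lies near the dashed line.

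In all, 692 genes had a called interaction, 333 higher and 359 lower, of which 317 differed by at least 1 on the log2 scale. A diet response was called in mutants only for 313 of them, in wild type only for 195, in both for 173 and in neither for 11. The count was 290 without wild-type low-sugar library B, 335 without mutant low-sugar library C and 281 without wild-type high-sugar library B. It was 271 without mutant high-sugar library A and 312 without mutant high-sugar library C. In the same order the numbers higher were 161, 165, 143, 144 and 158, and the numbers lower 129, 170, 138, 127 and 154. Without mutant low-sugar library B 590 were lower, and without mutant high-sugar library B 211 were higher. DESeq2 gave 1202, 480 higher and 722 lower, and the cuticle covariate 1226, 613 higher and 613 lower. Of the 1154 genes that rose in wild type 157 (13.6%) had an interaction of the opposite sign, a weaker or reversed response, and 32 one of the same sign. Their median log2 fold change was 0.73 in wild type and 0.41 in mutants. Of the 1164 that fell 124 (10.7%) had an opposite and 55 a same interaction, with medians of -0.66 and -0.58. DESeq2 gave 331 in place of 157, 58 in place of 32 and 108 in place of 55, and the cuticle covariate gave 222 in place of 124, 69 in place of 32 and 131 in place of 55. The count of 32 was 20 by the exon with the highest mean, and that of 55 was 84 with at least 5 CPM in 3 libraries and 35 with the letter as a block. In 20 simulated data sets with equal responses in both genotypes, opposite interactions averaged 0.2 and were at most 2. These sets drew each gene by itself, without the shared axis of spread within groups, and averaged 1341.8 wild-type calls against 2318 real ones. They thus set no bound on what the structure of the libraries can give. Regrouped real libraries called up to 1727 interactions of either sign, but that split kept the genotypes apart on high sugar. Its count therefore also holds the genotype effect there and is no measure of structure alone. Choosing genes by a call in wild type shrinks the mutant median by itself, in the simulated sets from 1.01 to 0.94 for risen and from -0.89 to -0.79 for fallen genes. The called genes there had larger changes than the real ones, so this is no exact measure of the real shrinkage. The medians of the fallen genes above shrink about as much, and so are no sign of a loss of response by themselves. These opposite counts fell to as few as 72 and 58 without wild-type low-sugar library B and wild-type high-sugar library B, and also moved by over 1.5 times without mutant low-sugar library C (95 and 77), mutant high-sugar library A (73 and 78) and mutant high-sugar library C (78 and 78). The first was 73 without wild-type high-sugar library B and 100 without wild-type high-sugar library C, and the second was 70 without wild-type low-sugar library B. The count of 32 moved by over 1.5 times without any 1 of 9 libraries, all but wild-type low-sugar library A and mutant low-sugar libraries A and B, and was as low as 9. The count of 55 did so without any 1 of 10 libraries, all but wild-type low-sugar library C and wild-type high-sugar library C, and ranged from 10 to 94.

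Among the genes whose change on sugar was lowest in mutants relative to wild type were CG9238 (Gbs-70E) by -3.35 ± 0.26, CG1638 by -3.07 ± 0.52, CG13315 by -2.93 ± 0.43, CG1774 by -2.66 ± 0.23 and the alkaline phosphatase Aph-4 (Alp4, 3R:26874651-26878262) by -2.44 ± 0.27. CG9238 went from 15.6 ± 3.23 to 188 ± 19.9 CPM in wild type, and from 8.51 ± 1.86 to 10.1 ± 1.05 CPM in mutants (SD, n = 3). CG3106 differed by -2.56 ± 0.45, with a fall called in mutants only. The difference was positive for the purine synthesis gene Prat2 (3L:6905099-6907976) by 2.95 ± 0.36, the peroxiredoxin Prx2540-1 (Prx6b), which has close paralogs, by 2.95 ± 0.39, both with a rise called in mutants only. The serine protease homolog CG18563, by 2.5 ± 0.25, fell from 11.1 to 4.33 CPM in wild type and rose from 5.53 to 12.2 CPM in mutants. CG33307 (2L:13839262-13841520), by 2.62 ± 0.2, fell from 62.4 to 29.0 CPM in wild type and rose from 31.5 to 90.2 CPM in mutants. CG10026, a lipid-transfer family member, and CG34316 had positive differences of 2.44 ± 0.41 and 2.29 ± 0.41 because a fall called in wild type was not called in mutants. CG10026 went from 11.3 to 1.62 CPM in wild type and from 9.39 to 7.21 CPM in mutants, and CG34316 from 16.9 to 3.29 and from 23.1 to 22.2 CPM. The growth inhibitor Thor rose more in mutants, by 1.47 ± 0.27 (adjusted p = 0.0102).

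Of 7 pentose phosphate genes 6 had a lower response in mutants (7 adjusted over the list alone; median -1.62, adjusted p = 9.9e-14, and 0.19 with an estimated correlation), Tal and CG8036 among them by -1.62 ± 0.21 and -1.72 ± 0.23. In fatty acid synthesis 6 of 16 were lower and 0 higher (9 and 1 adjusted over the list alone; adjusted p = 0.00035, and 0.5 with an estimated correlation), Gpdh by -1.0 ± 0.16. In glycolysis 3 of 12 were lower (4 adjusted over the list alone; adjusted p = 0.02, 0.55 with an estimated correlation, 0.1 by fry, 0.055 without mutant low-sugar library A and 0.056 without wild-type high-sugar library C), Pgi by -1.06 ± 0.19 and PyK by -1.1 ± 0.22. Of 15 Mondo-Mlx targets 5 were lower and 0 higher (7 and 1 adjusted over the list alone; adjusted p = 1.8e-05, and 0.25 with an estimated correlation). In serine and one-carbon metabolism 4 of 14 were higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.0016, and 0.5 with an estimated correlation), Gnmt (CG6188) by 2.14 ± 0.28 and Cbs by 1.09 ± 0.17. Other amino acid genes went both ways (4 of 21 higher, 2 lower, 8 and 4 adjusted over the list alone, adjusted p = 0.17), with hgo higher by 1.75 ± 0.24 and asparagine synthetase lower, at -1.85 ± 0.33. In lipolysis 3 of 19 were higher (5 adjusted over the list alone; adjusted p = 0.025, 0.67 with an estimated correlation, 0.12 by fry, and 0.052 without exons overlapping another gene), bmm, yip2 by 0.99 ± 0.14 and Mcad (CG12262) by 1.41 ± 0.23. That list was not called without wild-type low-sugar library A (0.083), mutant low-sugar library B (0.1) or C (0.091), or wild-type high-sugar library A (0.094).

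In ribosome biogenesis 9 of 20 genes had a lower response in mutants (13 adjusted over the list alone; adjusted p = 2.1e-09, and 0.5 with an estimated correlation), l(1)1Bi (Mybbp1A) by -1.15 ± 0.17 and pit by -0.95 ± 0.18. Among ribosomal protein genes 18 of 86 were higher and 0 lower (49 and 1 adjusted over the list alone; median 0.4, adjusted p = 3.2e-10, and 0.5 with an estimated correlation). DNA replication had 1 of 18 lower (1 adjusted over the list alone; adjusted p = 0.0074, 0.55 with an estimated correlation, and 0.1 by fry), and midgut markers had 1 of 14 lower, the proton pump subunit Vha100-4 by -1.21 ± 0.22 (6 adjusted over the list alone; adjusted p = 0.0033, 0.54 with an estimated correlation, and 0.14 by fry). In insulin and growth 3 of 19 were higher (3 adjusted over the list alone; adjusted p = 0.025, 0.5 with an estimated correlation, 0.051 by fry, 0.084 without mutant low-sugar library A, 0.068 without mutant high-sugar library A, and 0.065 both with the cuticle covariate and without 3 libraries apart). Of 20 antimicrobial genes 0 were called by edgeR, 0 also adjusted over the list alone, with a median of 1.6 (adjusted p = 0.0077, 0.75 with an estimated correlation, 0.33 by fry, and 0.11 without mutant high-sugar library A). The cuticle list had 1 of 76 higher (0 adjusted over the list alone; adjusted p = 0.0055, 0.86 with an estimated correlation, 0.53 by fry, 0.32 with the cuticle covariate, 0.14 without 3 libraries apart, 0.11 without wild-type low-sugar library B, 0.21 without mutant low-sugar library A and 0.16 without wild-type high-sugar library C). The covariate is the mean of this same list, so the loss with it is largely built in. Of 4 fat body markers 1 was lower (1 adjusted over the list alone; adjusted p = 0.031, 0.5 with an estimated correlation, 0.1 by fry, 0.23 without a filter on low counts, 0.083 without wild-type low-sugar library C, 0.084 without mutant low-sugar library A and 0.066 without mutant high-sugar library A). Of the 31 lists 14 were called by camera, 0 with an estimated correlation (2 at an unadjusted p under 0.05), and 7 by fry. Among single genes, Hsp83 was lower, at -1.95 ± 0.29, and Cyp28d1 and the sorbitol dehydrogenase Sodh-2 were higher, by 2.0 ± 0.2 and 1.56 ± 0.24.

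Of the remaining genes named in advance, Aldh-III was not called in any contrast (0.08, adjusted p = 0.661, for the wild-type diet response), nor was tobi (-0.82 ± 0.46, adjusted p = 0.224). InR rose in wild type by 0.57 ± 0.14 (adjusted p = 0.0107) and in mutants by 1.38 ± 0.14 (2.82e-05), and was higher in mutants on high sugar by 0.65 ± 0.14 (0.00752). Its interaction of 0.81 ± 0.19 passed in all 12 libraries (adjusted p = 0.0296), but not without any 1 of 9 libraries, all but mutant low-sugar libraries A and B and wild-type low-sugar library A (up to 0.08). The nuclear receptor Hnf4 did not change with diet in either genotype by the call threshold (-0.11, adjusted p = 0.645, in wild type, and 0.38, 0.0965, in mutants), but was higher in mutants on high sugar by 0.61 ± 0.16 (0.0243). That call was lost without wild-type high-sugar library A (0.0591) or B (0.107), or mutant high-sugar library A (0.0752), B (0.0672) or C (0.0571). Its interaction was not called (0.49 ± 0.22, adjusted p = 0.21).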

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

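The tests of library size, of a few genes taking most of the counts and of the normalization factor, the cuticle covariate, the fit without 3 libraries apart, the block within low sugar and the 20 splits that keep the high-sugar genotypes apart were chosen after their results or the data were seen, and the other tests before. The results here are those whose diet response differed between wild type and mutants by the test of the difference itself, 692 genes by edgeR. In this test 2 of 100 drawn splits of the genotype labels within each diet, of 200 possible and the real one included, called as many, and the highest other gave 1727 genes, more than the real one. This share excludes nothing, because 85 of the drawn splits mix the genotypes on high sugar, which puts that genotype effect into the residual, and they called at most 49 genes (median 0). Of the 20 splits that keep the genotypes apart on high sugar 3, the real one included, called as many. This share lies above 0.05, the lowest that 20 splits can give. But these splits all leave the genotype effect on high sugar, 1392 genes in its own contrast, inside the tested difference. They are thus no sets without an effect, and their share neither sets the count of 692 apart nor counts against it. Of the 8 among these 20 splits that part all lettered pairs on low sugar 2 called as many, the other with 981 genes being the real groups with genotype swapped in 1 diet. The highest split, with 1727, keeps the genotypes apart on high sugar and puts wild-type library A with mutant libraries A and C on low sugar, which follows cuticle gene levels. Its count can hold both the genotype effect on high sugar and a structure of the samples, and their shares were not told apart. The count was 290 without wild-type low-sugar library B, 335 without mutant low-sugar library C, 281 without wild-type high-sugar library B, 271 without mutant high-sugar library A and 312 without mutant high-sugar library C.

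The change on sugar was lower in mutants than in wild type for CG9238 (-3.35), CG1638 (-3.07), CG13315 (-2.93), CG1774 (-2.66), CG3106 (-2.56), Zw (-2.46), Aph-4 (-2.44), ATPCL (-2.18), Pgd (-1.99), desat1 (-1.33) and Gpdh (-1.0), as log2 differences between the responses. It was higher in mutants than in wild type for Prat2 (2.95), Prx2540-1 (2.95), CG33307 (2.62), CG18563 (2.5), CG10026 (2.44), CG34316 (2.29) and Thor (1.47). These genes kept the call without any 1 library and under the alternatives run on single genes. The lower limit of 1 on the log2 scale was run on counts of genes only. Zw, ATPCL, Pgd and Gpdh are reported Mondo-Mlx targets, a list partly chosen on these samples.

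For 4 other genes the call hung on single libraries. Cyp4e3 (4.55, adjusted p = 0.0453) was lost without any 1 of 9 libraries, all but wild-type low-sugar A and C and mutant low-sugar B (up to 0.115). CG6639 (2.67, 0.0361) was lost without any 1 of 9, all but mutant low-sugar B and C and mutant high-sugar C (up to 0.098). CG6296 (-2.54, 0.0478) was lost without any 1 of 8, all but wild-type low-sugar A and C, mutant low-sugar B and wild-type high-sugar A (up to 0.118). InR (0.81, 0.0296) was lost without any 1 of 9, all but wild-type low-sugar A and mutant low-sugar A and B (up to 0.08).

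The lists with a called difference are given by their median log2 difference. They were lower for pentose phosphate (-1.62), midgut markers (-0.69), ribosome biogenesis (-0.64), fatty acid synthesis (-0.58), DNA replication (-0.38) and Mondo-Mlx targets (-0.26). They were higher for ribosomal proteins (0.4) and serine and one-carbon metabolism (0.28). Of these, midgut markers and DNA replication were not called by fry (adjusted p = 0.14 and 0.1), with 1 of 14 and 1 of 18 genes called. The Mondo-Mlx list was partly chosen on these samples. Glycolysis (-0.33) was lost without mutant low-sugar library A (adjusted p = 0.055) or wild-type high-sugar library C (0.056). Fat body markers (-0.59) were lost without wild-type low-sugar library C (0.083), mutant low-sugar library A (0.084) or mutant high-sugar library A (0.066). Insulin and growth (0.34) was lost without mutant low-sugar library A (0.084) or mutant high-sugar library A (0.068), and antimicrobial genes (1.6) without mutant high-sugar library A (0.11). Lipolysis (0.1) was lost without wild-type low-sugar library A (0.083), mutant low-sugar library B (0.1) or C (0.091), or wild-type high-sugar library A (0.094). The cuticle list (0.51) was lost without wild-type low-sugar library B (0.11), mutant low-sugar library A (0.21) or wild-type high-sugar library C (0.16), and its adjusted p was 0.32 with the cuticle covariate, which is the mean of the list itself. With an estimated correlation 0 of these lists passed, where 2 of 31 had an unadjusted p under 0.05, and 7 of 31 passed by fry.

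In the interaction 18 of 86 ribosomal protein genes were called higher (median 0.4, 77 positive) and 9 of 20 ribosome biogenesis genes lower, and both lists lost the call with an estimated correlation (adjusted p = 0.5 for each). A scaling artifact stays open, since the lowest median of the list under the other scalings was 0.38, but these moved the median of all genes only to -0.02 and 0.05 and so could not have ended the pattern. Short transcripts stay open as well, because genes matched on exon length and level had a median of 0.15 (95% bootstrap interval over genes 0.02 to 0.25), and the bound that would exclude them was 0.202. Genes are not independent replicates, and this interval leaves out the spread between libraries. No biological explanation beyond genotype and diet was tested.

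Libraries of 1 group spread along a shared axis. The mean of the larval cuticle genes, a marker of moult stage, followed its first component (Pearson's r = -0.99, rho = -0.97, permutation p = 0.0015, adjusted over 3 tests 0.0045, r = -0.98 without wild-type and mutant low-sugar library A). Library size (r = 0.31, 95% interval -0.45 to 0.81, rho = 0.09, permutation p = 0.47, adjusted 0.47, r = 0.25 without mutant low-sugar libraries A and C) and a few genes taking most of the counts (r = 0.49, -0.26 to 0.87, rho = 0.48, permutation p = 0.24, adjusted 0.36, r = 0.22 without wild-type low-sugar libraries A and C) cannot be told apart from no relation with 12 libraries. This is consistent with larvae of slightly different age or moult stage in a group, as a hypothesis found and tested on the same data. With the cuticle mean as a covariate the interaction count was 1226, and cuticle level may be partly confounded with diet in wild type (group means 5.64 on low and 4.52 on high sugar), less so in mutants (4.94 and 4.5), and so with the interaction and with genotype on low sugar.

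Genotype differences shared by both diets could come from loss of Mlx or from the mutant's strain. A region carried over with the mutation is argued against as the main source, since 3.5% of the 200 shared calls lay within 2 Mb of Mlx (95% interval 1.4 to 7.1), 2.25% of the genes there against 1.99% of all (Fisher's exact test, p = 0.68). For the 7 shared calls inside that window, CG6271 and CG3348 among them, a carried-over region stays open. Strain differences elsewhere stay open for the other 193 calls and cannot be told apart from the loss of Mlx, because there is 1 control and 1 mutant line, and the same limit holds for the interaction.

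For the contrasts of 3 against 3 libraries the 10 splits are too few for a share under 0.05. All splits but the real one also mix the groups, which puts a real difference into the residual and lowers their counts. Low counts in them are therefore no support for the real grouping. In the wild-type diet response 1 split, the real one, called as many as 2318, and the highest other called 0. In the mutant diet response 1 split called as many as 2941, and the highest other called 2. In the genotype effect on high sugar 1 split called as many as 1392, and the highest other called 0. In the genotype effect on low sugar 2 splits called as many as 361, and the highest other, 459, grouped wild-type library A with mutant libraries A and C, which again follows cuticle level. Among the 4 splits that part all 3 lettered pairs there, the highest other called 0, and with the letter as a block within low sugar 996 genes differed, against 336 with the letter as a block in all 12 libraries. The labels do not say that the letters mark pairs.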

How the results depend on the processing

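The cuticle covariate, the fit without 3 libraries apart and the block within low sugar were chosen after seeing the data. Of the checks of single named genes 8157 kept direction and side of the threshold, 758 lost and 28 gained the call. For gene lists these numbers were 2597, 169 and 81, for counts and the Mlx level 532 stayed within bounds and 128 moved, and none reversed. A log2 fold change of at least 1, which by construction keeps fewer genes, left 594 (362 higher, 232 lower) for the wild-type diet response, 872 (422, 450) for mutants, 157 (76, 81) for genotype on low sugar, 499 (256, 243) on high sugar and 317 (176, 141) for the interaction. It left 119 and 94 shared diet calls, 58 and 41 shared genotype calls, and, of wild-type calls, 73 risen and 42 fallen genes with an opposite and 2 and 1 with a same interaction. DESeq2 called more unchanged genes on simulated data, which were drawn with the dispersions of edgeR. It gave 653 (337, 316) on low sugar, 1202 for the interaction (722 lower), 140 genotype calls lower on both diets, and 331 risen with an opposite and 58 risen and 108 fallen with a same interaction. The 6 low-sugar libraries alone gave 122 (56, 66), with fewer degrees of freedom. The block within low sugar gave 996 (514, 482). The cuticle covariate gave 296 lower on low sugar, 2298 (1097, 1201) on high sugar, 1226 (613, 613) for the interaction, 1142 diet and 149 genotype calls lower in both, 69 risen and 131 fallen with a same and 222 fallen with an opposite interaction. Risen genes with a same interaction were 20 by the exon with the highest mean, and fallen ones 84 with at least 5 CPM in 3 libraries and 35 with the letter as a block. Lists called with an estimated correlation were 3, 0, 2, 2 and 0 in the order of the contrasts, and by fry 7 for genotype on low sugar and 7 for the interaction. Except where the construction is named, the cause was not tested. With each library left out in turn, the wild-type diet response ranged from 1423 to 2361 (681 to 1249 higher, 690 to 1112 lower) and genotype on low sugar from 180 to 441 (77 to 236, 103 to 205). Genotype on high sugar ranged from 825 to 1123 (407 to 568, 415 to 610) and the interaction from 271 to 1021 (143 to 431, 127 to 590). Genotype calls shared by both diets ranged from 68 to 108 higher and 60 to 85 lower. Wild-type calls with an opposite interaction ranged from 72 to 226 and 58 to 151, and with a same one from 9 to 36 and 10 to 94. The mutant diet response ranged from 2025 to 2988, within bounds. Small changes can be missed at this depth and with 3 libraries per group, since on simulated data 17.2% of 2-fold and 71.7% of 4-fold interactions were recovered. Neither depth nor the number of libraries was varied there, so their shares in this limit were not tested. With library totals from 8924342 to 12507970 counts genes with few reads were left untested.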

Other observations

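CG14852 (3R:10391649-10392235) and CG3348, and the chromosomes of the shared calls below, were picked after their values were seen. CG14852 fell on sugar in wild type from 258 ± 29.2 to 29.0 ± 4.45 CPM and in mutants from 622 ± 78.2 to 283 ± 23.1 CPM (SD, n = 3). The log2 fold changes were -3.15 ± 0.15 and -1.14 ± 0.14, with an interaction of 2.02 ± 0.2 (adjusted p = 0.00032). Mutants had more of it on low sugar (1.27 ± 0.14, adjusted p = 0.000376) and on high sugar (3.29 ± 0.15, adjusted p = 7.53e-08).

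CG3348 (3R:23117257-23117931) lies near Mlx with the gene Hmu between them. It rose on sugar in wild type from 218 ± 55.1 to 765 ± 79.6 CPM and stood at 60.9 ± 20.9 and 56.8 ± 14.7 CPM in mutants (SD, n = 3). Its genotype log2 fold changes were -1.84 ± 0.29 on low sugar (adjusted p = 0.00555) and -3.75 ± 0.31 on high sugar (adjusted p = 2.13e-05), with an interaction of -1.91 ± 0.4 (adjusted p = 0.0211).

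The 200 genotype calls shared by both diets, without Mlx, lay on 2L (43), 2R (61), 3L (27), 3R (38) and X (29), with 0 on chromosome 4 and the others on unplaced sequence or heterochromatin. As shares of the genes tested these were 2.53% on 2L, 2.95% on 2R, 1.36% on 3L, 1.51% on 3R and 1.81% on X. Chromosome 4 had only 83 genes tested. The differences between these shares were not tested.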
